A study of Mus musculus with 6 samples.

How the data were processed

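Small RNA libraries from 6 samples of N2A cells were analysed, 3 given a control siRNA (si-NC) and 3 an siRNA against circCpsf6, both at 100 nM with a lipid reagent. Per the labels' protocols, cells grew in DMEM with 10% serum and 1% antibiotics, RNA was extracted with Trizol, and libraries were made from 1 ug of total RNA with the TruSeq small RNA kit. Samples were grouped by their titles. Per the submitters' processing notes the genome build was mm9. The aligner, the counting method, the normalization method and the miRNA reference release are not given in the sources used here.

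The values tested were the authors' normalized read numbers per entry, one column per library, treated as a score because they are normalized and rounded to whole numbers, per the file headers and the values. They are not raw read counts. Entry names carry suffixes read here as length and substitution variants, and entries whose names start with PC, which carry no miRNA name, are called predicted candidates here. The authors also deposited a fold change of the group means, its log2, and a p-value of a test between the groups, per the file headers. That fold is infinite for 122 entries whose si-NC mean is 0 and minus infinite for 103. These columns were used only for the counts credited to the authors' deposited table. Library totals ran from 2570449 to 3268351, and since they are normalized they do not give the read depth. In si-NC replicate 3 the step between low values was 3.86, and its total divided by that step was 666783, which is a hint of its depth. No such step was clear in the other libraries.

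The planned count test was replaced by the planned test for normalized values, since the unit was not counts. Of 178 rows that repeated the values of an earlier row, those with a value above 0 in at least 3 libraries, or with the same name apart from the variant suffix, were merged as copies, which left 1046 of 1080 entries. The 916 with a mean of 1 or more over the 6 libraries were tested by limma 3.58.1 (trended variance) in R 4.3.3 on log2(value + 1), with the group as the only term and Benjamini-Hochberg adjustment at 0.05. A log2 change is therefore on the log2(value + 1) scale, which can understate changes of low entries. Where a library is listed at or near 0, it can also exceed or reverse the change of the group means. miR-877-5p averaged 180 in si-NC and 168 in si-circCpsf6, yet its log2 change was 0.57, with si-NC replicate 3 at 19. Of 20 miRNA lists fixed before the data were examined, the 18 with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01 and adjusted over the lists, each miRNA entering as its more abundant arm, and again with an estimated correlation and with fry. Adjustment over the members of a list alone is given beside that over all entries. The 3p to 5p ratio of 188 hairpins was tested with limma. The share of the 10 most abundant miRNAs, the number of entries detected and the summed let-7 value were compared by two-sided exact permutation tests, for which 3 against 3 libraries cannot give a p under 0.1. The limma and camera steps were tested on simulated data with 200 changed entries among 916 and with the let-7 family lowered by 1 log2 unit, where 1 of 18 lists passed, the let-7 family. Entries were simulated independently of each other. These runs therefore cannot show how camera behaves when members of a list vary together.

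The rule for named miRNAs took those past the threshold, or else the 10 of smallest p with a mean of 10 or more, the 10 most abundant, and up to 4 of the most abundant members of each list. Members are named mainly for lists that passed a list test, and the other lists are given by their medians. miR-429, miR-214, mir-6236-p5, miR-96, miR-124, miR-126a, miR-132, miR-138, miR-194 and miR-880 were named, or singled out beyond that rule, after their values were seen. Alternatives were other pseudocounts (0.1 and 5), other filters on low values, each library left out in turn, the replicate number as a block, a robust variance, rescaled values, low values set to 20, mouse-named entries alone, identical rows kept apart, array weights, 1 residual component, and removal of each library's trend on GC content. The residual component was taken from what the group fit leaves over. It therefore leaves every log2 change as it was and only removes spread, which favours passing. Hairpin positions and arm GC content came from GENCODE M21 (GRCm38) by matching names, and GC content was known for 667 tested entries (72.8%), or 98.5% of those named as mouse miRNAs. Positions are on GRCm38, not on the authors' build. Calculations outside R used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.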

Results

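Small RNA was profiled by sequencing in N2A (Neuro2A) cells, a line derived from a mouse neuroblastoma. Of the 6 libraries, 3 came from cells given a control siRNA (si-NC) and 3 from cells given an siRNA directed at circCpsf6, a circular RNA, each siRNA at 100 nM. The comparison asks how the microRNA (miRNA) profile differs when circCpsf6 is silenced. The level of circCpsf6 itself was not analysed here, so the extent of silencing is not given for any library. Each library listed 1080 small RNA entries as the authors' normalized read numbers, and these summed to 3045133, 2926705 and 2570449 in si-NC replicates 1, 2 and 3 and to 2874209, 3268351 and 2880094 in si-circCpsf6 replicates 1, 2 and 3. Mouse-named miRNAs (754 entries) held 99.2% of the summed values, the remainder being 122 entries without a miRNA name, here called predicted candidates, and 204 entries named after miRNAs of other species. Because the values were normalized before deposit, the read depth is unknown and no counting intervals are given. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

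In the N2A miRNA profile, miR-27b-3p and the neuronal and neuroendocrine miR-7a-5p had the highest mean values in both groups. By mean share over all 6 libraries the most abundant was miR-27b-3p, which held 9.03% of the summed values in si-NC and 8.79% in si-circCpsf6. In si-circCpsf6 alone, miR-7a-5p had the higher mean. miR-27b-3p was listed at 255446 ± 96566 normalized reads in si-NC and 258378 ± 15250 in si-circCpsf6 (mean ± SD, n = 3 per group, as for all means given here). For miR-7a-5p the values were 169637 ± 75643 and 266929 ± 86621 (log2 change 0.72, or 0.31 without si-NC replicate 3, where it stood at 88548 against 182067 and 238295, and 0.47 without si-circCpsf6 replicate 2). Among the 10 most abundant miRNAs were also miR-7b-5p (73657 ± 26055 and 78234 ± 25533), the broadly expressed miR-21a-5p (60159 ± 23202 and 80799 ± 28643), and miR-741-3p, miR-881-3p and miR-470-5p of an X-linked cluster best known from testis. The members of that cluster had means of 84146, 79725 and 60523 in si-NC and 82061, 75144 and 52854 in si-circCpsf6. The others were miR-143-3p, miR-99b-5p and miR-30d-5p, at 69667, 66597 and 60374 in si-NC and 77164, 60070 and 65011 in si-circCpsf6. None of the 10 passed the limma test between the groups, and with 1 residual component as a covariate miR-7a-5p did (adjusted p = 0.0400, the highest over its alternatives being 0.938).

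The 10 most abundant miRNAs together made up 34.6 ± 7.25% of the summed values in si-NC and 36.9 ± 2.72% in si-circCpsf6, a difference of 2.30 percentage points (two-sided exact permutation p = 0.8, the smallest possible with 3 against 3 libraries being 0.1). In si-NC replicate 3 this share was 26.3%, against 39.6% and 38.0% in the other si-NC libraries, and without that library the difference was -1.87 points. An average of 738 ± 156 entries had a value of 1 or more in si-NC and 786 ± 66.3 in si-circCpsf6 (difference 48.7, exact permutation p = 0.8). The detected number was 558 in si-NC replicate 3, between 717 and 849 in the other libraries, and without si-NC replicate 3 the difference was -41.2.

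No single miRNA passed the test across all entries, and the miRNAs closest to it were mostly members of the let-7 family. Of the 10 entries with the smallest p-values among those with a mean of 10 or more, 7 were let-7 members, all lower in si-circCpsf6: let-7a, let-7b, let-7d, let-7f, let-7g, let-7i and miR-98. miR-5121, whose hairpin overlaps an exon of the ribosomal protein gene Rpl13a (GRCm38 chromosome 7, 45126918 to 45126991), was listed at 848, 898 and 2420 in the si-NC libraries and at 302, 205 and 423 in the si-circCpsf6 libraries. The remaining 2 were predicted candidates without an assigned miRNA. PC-3p-14533_73 was listed at 0 in each si-NC library and at 50, 47 and 76 in the si-circCpsf6 libraries, and PC-3p-11918_97 was listed at 0 in each si-NC library and at 30, 9 and 66 in the si-circCpsf6 libraries.

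By limma on log2(value + 1), 0 of 916 entries had an adjusted p under 0.05, the lowest being 0.0923 (PC-3p-14533_73), and 57 had an unadjusted p under 0.05 (30 higher and 27 lower in si-circCpsf6), against 45.8 by chance. These made up 6.22% of the entries, a share that ran from 5.46% to 14.4% with 1 library left out, the highest without si-NC replicate 3, and was 22.9% with array weights per library and 21.9% with 1 residual component as a covariate. In the authors' deposited table, 40 of 1080 entries had a p under 0.05 without adjustment, against 54 by chance, and 4 of these were let-7 members. The values of the groups did not overlap for 107 entries (11.7%, against 10% by chance). With si-NC replicate 3 left out, 4 entries passed (let-7f, let-7g and let-7i lower, PC-3p-14533_73 higher), with array weights per library 31, and with 1 residual component as a covariate 41, where the lowest adjusted p over the alternatives ranged from 0.00155 to 0.540. The residual component cannot change a log2 change, so its 41 calls come from a smaller spread alone. The array weights, estimated from the same libraries, were 0.146 for si-NC replicate 3 and 2.29 and 1.37 for si-NC replicates 1 and 2. The 31 calls therefore rest on giving si-NC replicate 3 little weight. In simulated libraries with the same spread, 0% of 200 miRNAs changed by 1 log2 unit were recovered, 42% of those changed by 2 and 67.5% of those changed by 3.

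The let-7 family, miRNAs that share a seed sequence, accumulate with differentiation and repress growth-promoting genes such as Hmga2 and Ras genes, was lower in si-circCpsf6 as a group in the list test with a preset correlation (limma's camera), but did not pass with an estimated one (adjusted p = 0.0501 with an estimated correlation). All 10 tested members had lower means in si-circCpsf6, with a median log2 change of -1.26, and for 9 of them the 3 si-NC libraries all lay above the 3 si-circCpsf6 libraries. let-7i-5p had the largest log2 change among them, at 3358 ± 1097 in si-NC and 948 ± 87.2 in si-circCpsf6 (log2 change -1.77, SE 0.31). let-7a-5p stood at 2573 ± 62.4 and 1193 ± 148 (-1.12, SE 0.24), let-7g-5p at 6895 ± 1913 and 2805 ± 95.3 (-1.26, SE 0.28), and miR-98-5p at 365 ± 83.0 and 128 ± 30.2 (-1.50, SE 0.38). let-7c-5p, by far the most abundant member, was listed at 41674 ± 2297 in si-NC and 37283 ± 2214 in si-circCpsf6 (-0.16, SE 0.24).

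With the preset correlation the adjusted p of the family was 4.88e-15, against an adjusted p = 0.0501 with an estimated correlation. fry, which tests whether the members move one way without comparing them with other miRNAs, gave an adjusted p of 0.00445. Adjusted over the list alone, 8 of 10 members were lower, namely let-7a, let-7b, let-7d, let-7f, let-7g, let-7i, the let-7j variant and miR-98, against 0 over all entries tested. let-7e (7489 ± 1752 and 4834 ± 94.9, -0.60) had an adjusted p over the list of 0.0564 and let-7c one of 0.513. Summed over the family, the value was 71696 ± 7614 in si-NC and 51163 ± 2299 in si-circCpsf6, or 71.4% of si-NC (exact permutation p = 0.1, the smallest possible). The entry for let-7c-5p had the same values as one named as a let-7a-5p variant with a single substitution, which was merged with it as a copy. How reads were assigned between near-identical members is not given, so their split is uncertain. Of 7 entries listed by name as overlapping ribosomal, transfer or small nucleolar RNA, as a sign of RNA breakdown, 5 had lower values in si-circCpsf6 as well (median log2 change -0.77, camera adjusted p = 0.0180, but adjusted p = 0.689 with an estimated correlation). The overlap itself was not checked here.

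**Figure D1:**
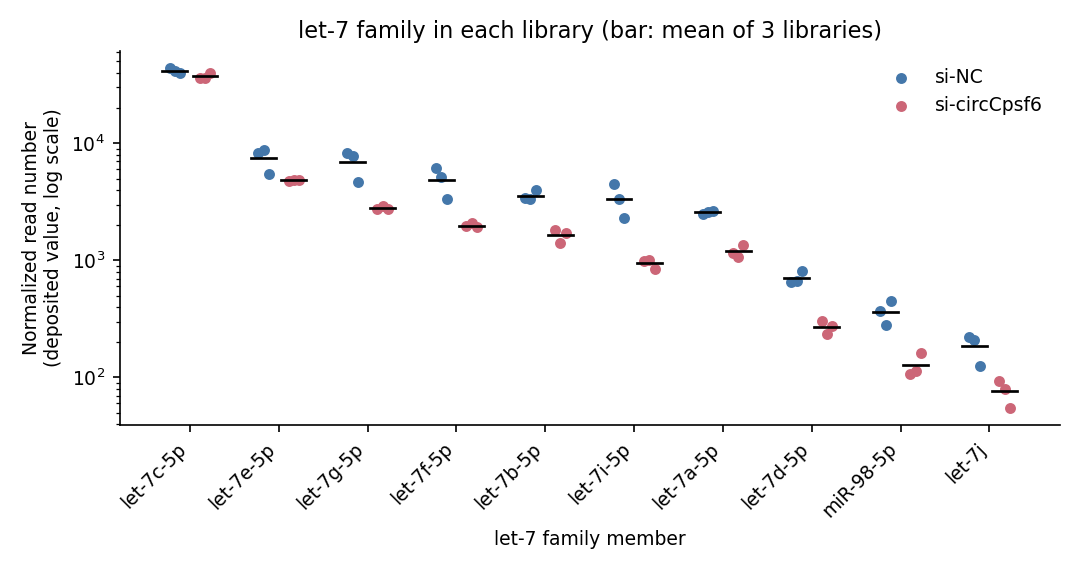
Normalized read number (deposited value, logarithmic axis) of the 10 tested let-7 family members in each library, with 3 si-NC libraries in blue and 3 si-circCpsf6 libraries in red and black bars for the means. let-7i lies near 3358 in si-NC and 948 in si-circCpsf6, while the groups lie close together for let-7c (41674 and 37283).

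The let-7 members lie at separate places in the genome (GRCm38, placed by hairpin name). The let-7i hairpin lies on chromosome 10 at 122985640 to 122985724 in an exon of the transcribed pseudogene D630033A02Rik. The let-7g hairpin lies on chromosome 9 at 106178840 to 106178927 in an intron of Wdr82. A copy of let-7f lies on chromosome X at 151912346 to 151912428 beside miR-98 at 151913214 to 151913321, both in an intron of Huwe1. let-7d, a copy of let-7f and a copy of let-7a lie together in an exon of the long noncoding RNA 6720427I07Rik on chromosome 13, between 48536012 and 48538272. let-7b and a copy of let-7c lie on chromosome 15 in an exon of Lncppara, at 85707319 to 85707403 and 85706603 to 85706697. These members differed in their log2 change, -1.11 for let-7b and -0.16 for let-7c, which has another copy on chromosome 16 in an intron of Mir99ahg (77599657 to 77599750).

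miRNAs of the imprinted Dlk1-Dio3 cluster on chromosome 12, expressed from the maternal allele and abundant in brain and placenta, were higher in si-circCpsf6 as a group with the preset correlation (camera adjusted p = 3.32e-06), but not with an estimated one (adjusted p = 0.744 with an estimated correlation). Of 45 tested members, 40 had higher log2 values and 5 lower, with a median log2 change of 0.99. The most abundant was miR-127-3p, whose hairpin lies opposite an exon of Rtl1 (GRCm38 chromosome 12, 109592846 to 109592915), at 453 ± 298 in si-NC and 721 ± 173 in si-circCpsf6. miR-300-3p was at 160 ± 107 and 301 ± 71.5, miR-541-5p at 230 ± 176 and 277 ± 60.7, and miR-379-5p at 156 ± 103 and 239 ± 31.6. The tested members summed to 3901, 1534 and 1549 in si-NC replicates 1, 2 and 3. They summed to 4373, 2826 and 4641 in the si-circCpsf6 libraries, so si-NC replicate 1 lay within the si-circCpsf6 range. fry gave an adjusted p of 0.398, and 0 members passed adjusted over the list alone or over all entries. The number of members listed at 0 was 3, 12 and 21 in the si-NC libraries and 5, 6 and 7 in the si-circCpsf6 libraries. When the library with 21, si-NC replicate 3, was left out, the median was 0.68 (camera adjusted p = 0.00209, the range over all alternatives being 1.01e-11 to 0.744). Without si-NC replicate 1 the median was 1.42.

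Epithelial miRNAs of the miR-200 family, which maintain the epithelial state by repressing Zeb1 and Zeb2, were low in N2A cells, and their list was lower in si-circCpsf6 with the preset correlation (camera adjusted p = 0.00239, but adjusted p = 0.689 with an estimated correlation). miR-200a-3p was listed at 69, 141 and 58 in si-NC and at 25, 9 and 0 in si-circCpsf6, and miR-429-3p from the same cluster at 19, 23 and 27 and at 6, 0 and 0. miR-200c-3p averaged 52 ± 30.6 in si-NC and 11 ± 4.58 in si-circCpsf6, and miR-200b-3p was listed at 74, 169 and 0 in si-NC and at 13, 9 and 0 in si-circCpsf6, a log2 change of -2.17 that was -4.44 without si-NC replicate 3 and -0.74 without si-NC replicate 2. The hairpins of miR-200a, miR-200b and miR-429 lie in an intron of Ttll10 on chromosome 4 (GRCm38, 156053905 to 156055750). miR-375-3p, a miRNA of pancreatic islets and neuroendocrine cells in the same list, was at 165 ± 66.7 in si-NC and 270 ± 46.8 in si-circCpsf6. Of the 6 tested members of the list, 5 were lower, with a median log2 change of -2.39, which ran from -3.49 with a pseudocount of 0.1 to -0.72 with values under 20 set to 20. Adjusted over the list alone, miR-200a and miR-429 were lower, against 0 members over all entries. The list no longer passed without si-NC replicate 3 (median -2.85, adjusted p = 0.0609, the range over all alternatives being 2.96e-04 to 0.689).

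Entries listed by name as overlapping ribosomal, transfer or small nucleolar RNA were lower in si-circCpsf6 for 5 of 7 members (median log2 change -0.77, camera adjusted p = 0.0180, but adjusted p = 0.689 with an estimated correlation). The entry mir-6236-p5 was at 154 ± 21.8 in si-NC and 42.7 ± 18.6 in si-circCpsf6 and a variant of mir-6240-p3 at 1902 ± 1469 and 469 ± 92.7, and both were lower adjusted over the list alone, against 0 over all entries. The more abundant miR-3968 variant, miR-1983 and miR-1839-5p were at 2255, 3146 and 2890 in si-NC and 3734, 2554 and 1642 in si-circCpsf6. The list did not pass without si-NC replicate 2 (median -0.16, adjusted p = 0.109), without si-circCpsf6 replicate 1 (-0.86, 0.115) or without si-circCpsf6 replicate 2 (-0.87, 0.0781), within a range over all alternatives of 0.00842 to 0.689.

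Mesenchymal and endothelial miRNAs were higher in si-circCpsf6 for 6 of 6 members (median log2 change 0.49, camera adjusted p = 0.0386, but adjusted p = 0.744 with an estimated correlation). miR-214-3p, processed from the Dnm3os transcript, was at 550 ± 311 and 1276 ± 183, miR-199a-5p at 3300 ± 1362 and 5334 ± 1237, and miR-145a-5p, a smooth muscle and fibroblast miRNA, at 9761 ± 2580 and 12437 ± 1378. The most abundant member, miR-143-3p, differed less (69667 ± 17219 and 77164 ± 12302, log2 change 0.16). Means of miR-126a-3p were close together, at 3505 in si-NC and 3597 in si-circCpsf6. No member passed adjusted over the list alone or over all entries. The list passed without si-NC replicate 1 but not without any other single library, with a median of 0.25 and an adjusted p of 0.107 without si-NC replicate 3 and adjusted p-values of 0.0621, 0.115, 0.0670 and 0.174 without si-NC replicate 2 and si-circCpsf6 replicates 1, 2 and 3 (range over all alternatives 0.00866 to 0.744).

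The rodent-specific miRNA cluster in an intron of Sfmbt2 had 24 of 35 members lower in si-circCpsf6, with a median log2 change of -0.15 (camera adjusted p = 0.0469, but adjusted p = 0.744 with an estimated correlation). miR-669c-5p, its most abundant member, was at 10049 ± 2127 and 7531 ± 1223, and miR-467b-5p at 6203 ± 2815 and 4618 ± 435. No member passed adjusted over the list alone or over all entries. Without si-NC replicate 3 the median was 0.16 in the opposite direction (adjusted p = 0.153), and the list did not pass without si-circCpsf6 replicate 2 or 3 either (medians -0.060 and -0.23, adjusted p-values 0.437 and 0.0648, range over all alternatives 1.16e-04 to 0.744).

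**Figure D2:**
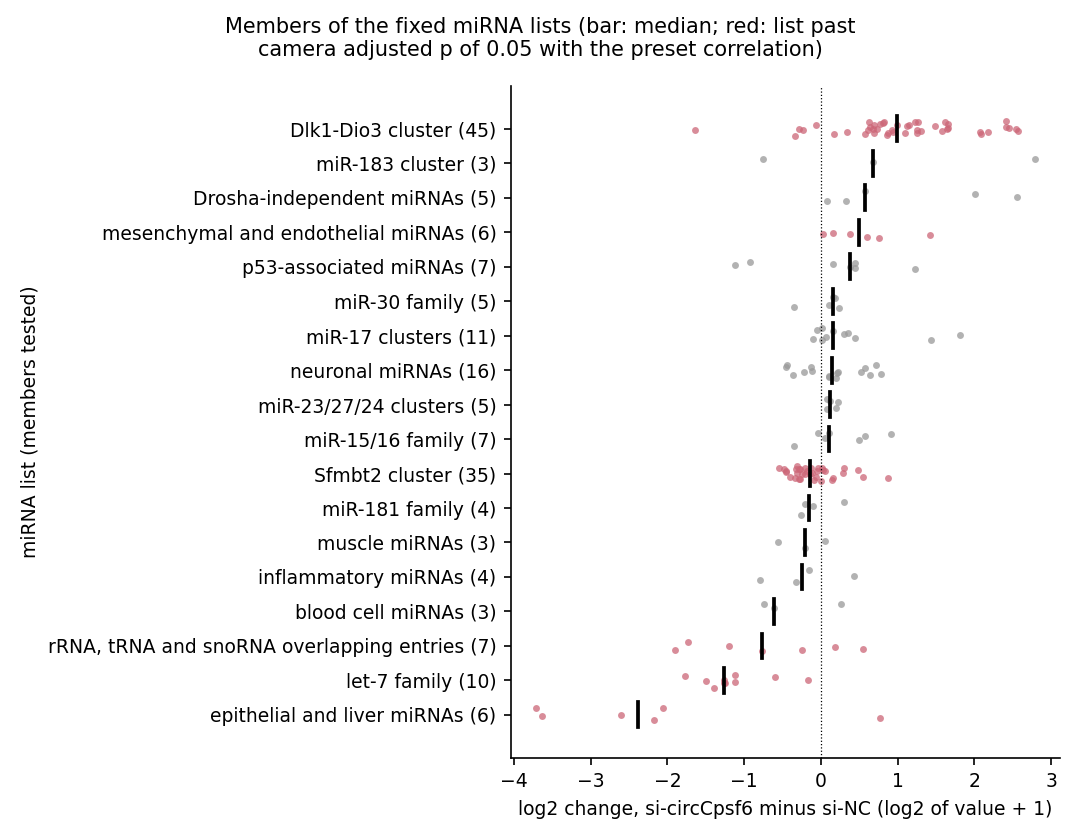
log2 change in si-circCpsf6 against si-NC (horizontal axis, log2 of value + 1) of each tested member of the 18 miRNA lists, with black bars for list medians and red points for the 6 lists past an adjusted p of 0.05 in camera with the preset correlation. The 10 let-7 members all lie below 0 around a median of -1.26, and 40 of the 45 Dlk1-Dio3 members lie above 0. None of the 6 passed with an estimated correlation.

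Neuronal miRNAs as a group did not pass the test against the other miRNAs. Of 16 members 10 were higher, with a median log2 change of 0.15 (camera adjusted p = 0.685, the median being 0.052 without si-NC replicate 3 and 0.058 without si-NC replicate 1), whereas fry gave an adjusted p of 0.00638. No member passed adjusted over the list alone or over all entries. The brain-enriched miR-124-3p was at 319 ± 219 and 467 ± 221, miR-138-5p at 4735 ± 1933 and 7823 ± 1285, and the activity-induced miR-132-3p at 2404 ± 98.0 and 3488 ± 532. These 3 were picked after their values were seen, and 6 members were lower. Among the lower members was the abundant miR-218-5p, at 22617 ± 11189 in si-NC and 18727 ± 6125 in si-circCpsf6.

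The growth-associated miR-17 clusters (median log2 change 0.15, camera adjusted p = 0.400) and the miR-15/16 family (0.10, 0.496) did not pass with all libraries. Without si-NC replicate 3 both did, with medians of 0.59 (adjusted p = 0.0425) and 0.73 (0.0128), where the adjusted p reached 0.979 over the alternatives for both. The miR-17 median was 0.051 without si-NC replicate 1 and 0.063 without si-circCpsf6 replicate 1. The p53-associated miRNAs had a median of 0.38 while the test pointed down (adjusted p = 0.769), since miR-192-5p (4229 ± 2138 and 1821 ± 450) and miR-194-5p (1604 ± 476 and 830 ± 142) were lower and the other 5 members were higher. The inflammatory miRNAs had a median of -0.24 (0.400), with miR-146a-5p at 3826 ± 801 and 2213 ± 427. Medians and camera adjusted p-values of the other families were 0.16 and 0.992 for miR-30, -0.16 and 0.545 for miR-181, 0.12 and 0.734 for the miR-23/27/24 clusters, and 0.57 and 0.400 for the Drosha-independent miRNAs, which passed with 1 residual component as a covariate (adjusted p = 0.0214, the highest over the alternatives being 0.744). The Drosha-independent median was that of miR-877-5p, whose mean was lower in si-circCpsf6 (180 in si-NC and 168 in si-circCpsf6). For markers of other cell types the medians and camera adjusted p-values were -0.62 and 0.564 for blood cells and -0.21 and 0.586 for muscle. The miR-183 cluster had a median of 0.69 (0.496), and its member miR-96-5p was listed at 0 in all si-NC libraries and averaged 6.33 in si-circCpsf6, the single member of these lists past the threshold when adjusted over the list alone, against 0 over all entries. With 1 library left out, the p53 median was 0.034 without si-NC replicate 3 and 0.11 without si-NC replicate 2, the miR-183 median 0.26 without si-NC replicate 2 or 3 and 1.55 without si-NC replicate 1, and the blood cell median -0.064 without si-NC replicate 2 and -1.13 without si-circCpsf6 replicate 1. The pluripotency clusters had 0 tested members and the oligodendrocyte list 2, too few for a test.

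The balance of the arms of a hairpin was compared for 188 hairpins with both arms measured. By limma on the log2 ratio of the 3p to the 5p arm, 0 hairpins had an adjusted p under 0.05 (the lowest 0.697), and 7 had an unadjusted p under 0.05, against 9.4 by chance. Without si-NC replicate 3, miR-880 alone passed (adjusted p = 0.0109), a hairpin whose 5p arm was listed at 0, 0 and 54 in the si-NC libraries and whose 3p arm averaged 29496 in si-NC and 29646 in si-circCpsf6.

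si-NC replicate 3 stood apart from the other libraries. Values of 0 were listed for 502 entries in it, against 200 to 333 in the others, and only 16 entries had values from 1 to 18, against 180 to 312. Whether low values were set to 0 before deposit is not given. A 0 in si-NC replicate 3 therefore need not mean absence, which bears on every count of zeros or detected entries that includes this library. Of its 242 values below 150, 84.3% were rounded whole multiples of 3.86, against 25.5% by chance, while no step exceeded chance by over 17.1 percentage points in the other libraries. Among 201 miRNAs with a mean of 1000 or more, its log2 deviation from the other si-NC libraries had an SD of 1.14, against 0.540 for si-circCpsf6 replicate 3 measured the same way. Across 345 miRNAs, which are not independent replicates, the deviation was lower at higher GC content of the hairpin arm (Spearman rho -0.36, against -0.17 for si-circCpsf6 replicate 3).

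**Figure D3:**
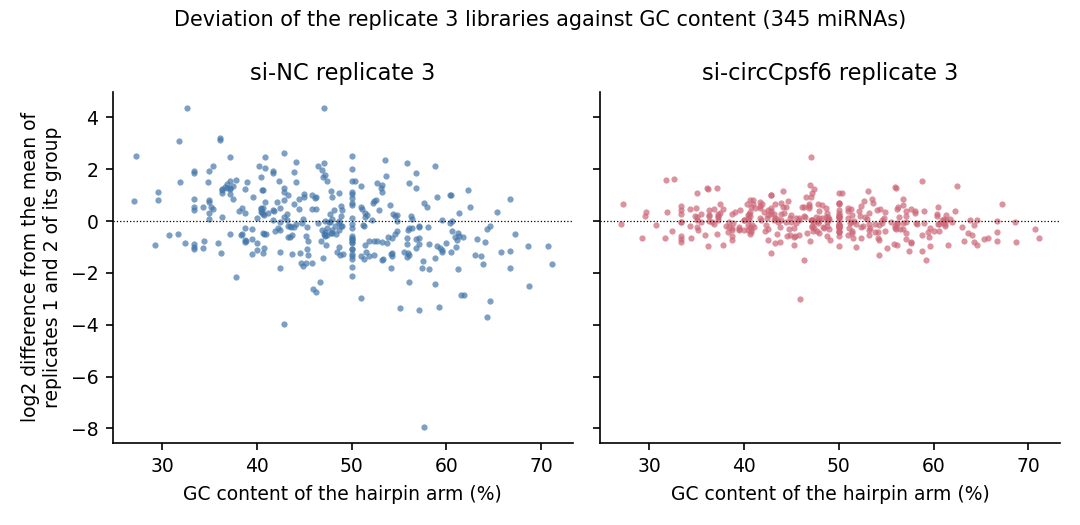
log2 difference of a replicate 3 library from the mean of replicates 1 and 2 of its group (vertical axis) against the GC content of the hairpin arm in percent (horizontal axis), each point being 1 of 345 miRNAs with a mean value of 100 or more, for si-NC (left) and si-circCpsf6 (right). The points of si-NC replicate 3 spread further and slope downwards (Spearman rho -0.36), against -0.17 for si-circCpsf6 replicate 3.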

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

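The rescaled values, the robust variance, low values set to 20, mouse-named entries alone, identical rows kept apart, array weights, the residual component, both GC settings, the list tests at other pseudocounts or without a filter, and the let-7 sum were chosen after the data were seen. Other count tests, count normalizations and thinning, intended for raw counts, were not run, since the values are not counts. For single miRNAs, 19 of 22 alternatives gave 0 calls. The exceptions gave 31 (array weights) and 41 (1 residual component), and leaving out 1 library gave 0 to 4, the 4 without si-NC replicate 3. Of the lists, 6 passed in the main test, 0 with an estimated correlation, 2 with fry, and 3 to 6 with 1 library left out, the 3 without si-circCpsf6 replicate 2. Every other split of the 6 libraries into 3 and 3 also gave lists at the preset correlation, from 1 to 5. The let-7 median stayed between -1.34 and -1.12, with an adjusted p under 0.05 in 20 of 21 alternatives, the exception being the estimated correlation (adjusted p = 0.0501). The summed let-7 difference was -23718, -17682 and -21043 with rescaling to a common total, a common upper quartile and the median of ratios, with all 10 members lower. Shifted hairpins numbered 0 to 1 with 1 library left out. As a replicate block, the replicate number gave 0 miRNAs (lowest adjusted p 0.185, 87 unadjusted), 6 lists and 0 hairpins. Deviations of same-numbered libraries correlated at 0.05, 0.48 and 0.40, against -0.44 to 0.18 for libraries of different numbers. A structure shared by the libraries numbered 2 and by those numbered 3 is therefore not excluded. The labels do not pair the samples, so the main tests assumed no pairing. The block changed no list count.

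Of the results that changed direction, the Sfmbt2 list passed in the main test and the miR-15/16 and Drosha-independent lists in 1 alternative each, and the cause was not tested beyond the removal of the library named. With 1 library left out, the top-10 share difference ran from -1.87 to 4.78 points (-0.24 for the single most abundant miRNA) and the difference in entries detected from -41.2 to 99.8. List medians ran from -0.25 to 1.26 (Drosha-independent), -0.41 to 0.16 (Sfmbt2), -0.48 to 0.072 (inflammatory), -0.11 to 0.73 (miR-15/16), -0.26 to 0.017 (miR-181), -0.084 to 0.44 (miR-23/27/24), -0.071 to 0.18 (miR-30) and -0.48 to 0.12 (muscle). Log2 changes of mmu-miR-125b-5p ran from -0.055 to 0.39, of mmu-miR-218-5p from -0.47 to 0.16, of mmu-miR-27b-3p from -0.11 to 0.37, of mmu-miR-30d-5p_R+2 from -0.26 to 0.43, of mmu-miR-467b-5p_L-1R+2 from -0.53 to 0.0082, of mmu-miR-467e-5p from -0.21 to 0.44, of mmu-miR-541-5p from -0.15 to 1.25, of mmu-miR-669a-3p from -0.47 to 0.37, of mmu-miR-741-3p from -0.32 to 0.25, of mmu-miR-7b-5p from -0.20 to 0.35, of mmu-miR-881-3p_1ss22AT from -0.25 to 0.016 and of mmu-miR-99b-5p from -0.41 to 0.14. With array weights mmu-miR-143-3p_R+1 was at -0.013 and the others at 0.11 (miR-218), -0.15 (miR-27b), -0.21 (miR-30d), -0.020 (miR-541), 0.34 (miR-669a), -0.34 (miR-741) and -0.23 (miR-7b), with a common total -0.0051 (miR-27b), -0.064 (miR-467e) and -0.051 (miR-741), and with the GC trend removed 0.038 (miR-881). Of 373 list values, 328 kept direction and side of the threshold, 30 no longer passed, 4 newly passed and 11 reversed, and of 1138 values of 52 named miRNAs these numbers were 1063, 0, 39 and 36. The median of all entries was 0.09 as deposited and 0.01, 0.15 and 0.07 with the rescalings above. Depth limits are unknown apart from the step of si-NC replicate 3.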

Other observations

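The tests by genomic cluster, of si-NC replicate 3 and of an epithelial source were chosen only after the results were seen. Grouped by genomic neighbourhood, with hairpins within 10 kb of each other, 15 clusters had at least 3 tested members. The cluster of miR-200a, miR-200b and miR-429 on chromosome 4 was lower (median log2 change -3.64, camera adjusted p = 0.00354, but adjusted p = 0.759 with an estimated correlation). The X-linked cluster of miR-322, miR-351, miR-450a, miR-450b, miR-503 and miR-542, miRNAs induced in muscle differentiation and cell cycle exit, was higher (0.56, 6 members, adjusted p = 0.0307, but adjusted p = 0.759 with an estimated correlation), with miR-322-5p at 5573 ± 1136 in si-NC and 8233 ± 1102 in si-circCpsf6. A cluster of miR-344 members was lower (-0.63, 3 members, adjusted p = 0.0451, but adjusted p = 0.759 with an estimated correlation). The parts of the Dlk1-Dio3 cluster, with 12 and 32 tested members, were higher as groups (medians 1.14, adjusted p = 0.0307, and 0.96, adjusted p = 3.69e-05), though some members of each were lower. The Sfmbt2 cluster was lower (-0.16, adjusted p = 0.0307). Each of these also had an adjusted p = 0.759 with an estimated correlation. The 17 members of the X-linked cluster that holds the abundant miR-741, miR-881 and miR-470 had a median of 0.07 (adjusted p = 0.986).

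miR-192-5p and miR-194-5p, expressed from shared transcripts in liver and gut epithelium, were highest in si-NC replicate 2, at 6565 and 2105, as were miR-200a (141), miR-200b (169) and miR-200c (87), whereas miR-429 (19, 23 and 27 in si-NC replicates 1, 2 and 3) and miR-141 (5, 11 and 27) were highest in si-NC replicate 3. The predicted candidate PC-3p-14533_73 was listed at 0 in each si-NC library and above 0 in each si-circCpsf6 library. Sequences of these candidates were not analysed here, so their origin, the transfected siRNA included, was not examined.

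The lower let-7 family in si-circCpsf6 was weighed against technical explanations, and rescaling the libraries to a common total or upper quartile left the family at 67.8% and 74.8% of its si-NC sum. With each library's trend on GC content removed, the median let-7 change was -1.21, or 0.965 of the uncorrected one. The arms of the let-7 members ran from 34.4% (let-7j) to 60.9% GC (let-7e), so removing a trend could hardly move their median. This removal therefore decides little, and other sequence biases were not tested. Without si-NC replicate 3, the library with the fewest entries detected, the let-7 median was -1.32, or 1.05 of that with all libraries. That argues against this library as the whole cause of the size of the change, although the list call itself is lost with an estimated correlation (adjusted p = 0.0501 with all libraries). RNA quality stays open, because 5 of 7 entries listed by name as overlapping ribosomal, transfer or small nucleolar RNA had lower values as well (median -0.77, adjusted p = 0.689 with an estimated correlation). The median of that list was -0.16 without si-NC replicate 2, where the let-7 median was -1.16. Without any other single library the list median ran from -1.10 to -0.58. RNA from an epithelial source in the si-NC libraries also stays open, by the ratio of the excess over si-circCpsf6 in si-NC replicate 2 to that in replicate 1. That ratio reached 1.11 among let-7 members and ran from 1.24 (miR-429) to 4 in the 5 of 6 tested members of the epithelial list that had an excess (miR-375 had none). The gap was 0.125, against an SD of 0.189 of the let-7 ratios. Chance stays open as well: 1 of the 10 splits of the 6 libraries, the real one, gave 6 or more lists, the others giving 1 to 5, and 10 splits cannot give a share under 0.1 (the let-7 test at the preset correlation had a -log10 p of 15.6 in the real split and at most 3.21 in the others). A batch shared by the libraries of a group and an effect of the siRNA, on circCpsf6 or on other targets, cannot be told apart in this design, so a lower level of mature let-7 after silencing of circCpsf6 is a hypothesis that these data may motivate but do not settle.

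The deviations of si-NC replicate 3 and si-circCpsf6 replicate 3 from their group mates correlated at 0.741 across 345 miRNAs. That argues against sampling noise alone as the reason that si-NC replicate 3 stands apart, because sampling noise is independent between libraries. A structure shared by the libraries numbered 3, such as a batch, would also give this correlation. The labels do not say what the replicate number marks, so such a structure stays open as a reason that si-NC replicate 3 stands apart. A base composition bias is a candidate explanation for part of it, since the deviation fell with arm GC content (Spearman rho -0.362 across miRNAs). Measured against the mean of all 6 libraries, the slope of si-NC replicate 3 was -0.41 log2 units per 10% GC. It was 0.15 and 0.13 in the other si-NC libraries. All slopes share that mean, so the positive ones are partly fixed by the negative one. No biological explanation was tested for this library.

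For single miRNAs and for arm ratios the real split of the libraries gave 0 calls and the highest other 0, so that 10 of 10 splits gave as many by construction and the count decides nothing. At an unadjusted p under 0.05, si-NC replicates 1 and 2 with si-circCpsf6 replicate 2 against the rest gave 21.2% of the entries tested, against 6.22% in the real split. With 1 residual component removed, 2 of 10 splits gave as many as the 41 of the real one (4.48% of the entries tested), and the highest other, again si-NC replicates 1 and 2 with si-circCpsf6 replicate 2, gave 16.3%. Both counts point to a structure of the samples other than their groups; 10 splits cannot give a share under 0.1 in any of these.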
